A study of Rattus norvegicus with 6 samples.

How the data were processed

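Gene expression was measured by sequencing of polyadenylated RNA from femur tissue of Wistar rats, a common outbred laboratory strain. The 6 libraries fall into 2 groups of 3, called control and CSD (chronic sleep deprivation) here, as the sample titles and treatment labels give them. The labels do not say whether the 3 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may in part be technical. The bone compartment, and whether marrow was removed, are not given in the sources used here.

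The authors deposited 1 table of raw read counts per gene, with 1 column per library. Reads were processed with HISAT2 2.2.1, HTSeq 0.12.4 and the rn6 build, per the submitters' processing notes; the roles of these tools, the annotation release, trimming and the strand setting are not given in the sources used here. The table has 32545 gene rows and 5 closing rows that name no gene. The closing rows stayed out of library sizes and tests. They held most of the reads: the row for reads outside any annotated feature took 45.5% to 47.1% of a library, reads with more than 1 alignment 8.56% to 9.46%, reads below the mapping quality limit 3.11% to 3.69%, unaligned reads 2.90% to 3.81% and ambiguous reads 0.624% to 0.750%. Genes received 36.2% to 38.2% of the reads. A strand setting that did not match the library would move reads to the first of these rows, but the counting mode was not tested here. Without a known strand setting, reads of overlapping and antisense genes cannot be told apart.

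Gene rows are identified by Ensembl gene IDs alone. The rat gene table used here holds 47357 genes with symbols but pairs none of them with an Ensembl ID, and 0 of the 32545 IDs could be matched. No gene is named for that reason, no position or annotation is given, and the gene lists fixed before the data were examined were not tested: 20 pathway lists (among them bone formation and PI3K/AKT signalling) and 15 cell type lists. The rule for genes named in the text, fixed at the same time, asked for symbols and, where no gene passed, for the genes with the smallest unadjusted p in each direction. It was applied to IDs, limited to 2 per direction.

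Genes with enough counts were kept with edgeR's filterByExpr at its defaults, which left 13431 genes holding 99.8% of the gene counts. Libraries were scaled with TMM factors (0.912 to 1.07). The main test was edgeR 4.0.16's quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) of CSD against control with no covariate, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Log2 fold changes are CSD minus control with a prior count of 0.125, and their standard errors (SE) are the absolute log2 fold change divided by the square root of F. CPM are gene counts scaled to library size with the TMM factors, in the usual unit. Log2 CPM with a prior count of 2 were used for correlations, for principal components and for the clustering of the 1000 most variable tested genes (average linkage on 1 minus Pearson's r, cut into 3 modules). The clustering and the group of genes with a log2 fold change above 3 were chosen after the data were examined. Single values per library were compared by an exact two-sided permutation test. With 3 libraries against 3 this test cannot give less than 0.1. R was version 4.3.3, limma 3.58.1 and DESeq2 1.42.0.

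The test was checked on simulated counts for the tested genes, drawn with the real means, library sizes and gene-wise dispersions but with genes independent of each other. The 200 changed genes were drawn only from those above a minimum mean count, so the shares called do not cover genes with few reads. Among them edgeR called 64.0% of those changed by 1 on the log2 scale, 100% at 2, 100% at 3 and 98.0% at 4, with the right sign. It called 11 of 13231 unchanged genes. DESeq2 called 72.0%, 100%, 100% and 98.0% of the changed genes and 40 of the unchanged ones. With no gene changed edgeR called 0 of 13431 and DESeq2 called 12. The changed genes were drawn without regard to their spread within groups. The shares called therefore need not hold for genes that vary widely within a group. In the real data no gene passed the main test, although 92 had a fitted log2 fold change above 3.

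Alternatives, fixed before the data were examined, were other scalings, other filters, DESeq2, limma-voom with and without quality weights, robust edgeR, other thresholds, the replicate number of the titles as a block and leaving out each library in turn. The labels do not say that a shared replicate number marks a litter, cage or day. The ages in the sample labels rise by 1 week per library from 12 weeks (control 1) to 17 weeks (CSD 3), whereas the series description gives 12 weeks. Labelled ages do not overlap between the groups, so telling age from group would rest on an assumed form of the age trend. Age was therefore not a covariate.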

Results

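The series asked whether chronic sleep deprivation (CSD) alters gene expression in the bone of growing rats; its title names bone formation and PI3K/AKT signalling, a kinase pathway of growth and survival. Femur RNA of 3 control and 3 CSD libraries was compared. Libraries held 23109469 to 25551753 reads in all rows of the table and 8366443 to 9572898 reads in genes. Of the 32545 genes, 19514 had at least 1 read, and 16550 to 17089 were detected per library. The tested genes had a median of 211 reads per library. The share of reads assigned to genes was 36.4% ± 0.303 (SD, n = 3) in controls and 37.6% ± 0.527 (SD, n = 3) in CSD, higher in each CSD library than in each control (exact permutation test, p = 0.1, the smallest possible). The 10 most abundant genes took 15.0% to 19.6% of gene counts, and the most abundant gene 3.73% to 6.34%.

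Libraries of one group resembled each other more than libraries of different groups. The Spearman correlation over 13431 genes averaged 0.973 for the 6 pairs within groups (0.965 to 0.981) and 0.957 for the 9 pairs between groups (0.947 to 0.971; one-sided exact permutation test, p = 0.1, the smallest possible). The difference in means was 0.0164, and it fell to 0.00750 with no filter and to 0.00939 without the 92 high-fold genes described below. By correlation control 1 was the control nearest to the CSD libraries. It correlated at 0.970 and 0.972 with the other controls and at 0.969, 0.966 and 0.971 with CSD 1, CSD 2 and CSD 3. CSD 1 and CSD 3 correlated at 0.965 with each other, less than either did with control 1. The first principal component of the 1000 most variable genes held 57.8% of their variance and placed all 3 CSD libraries on one side of all 3 controls (exact permutation test, p = 0.1, the smallest possible), with control 1 nearest to the CSD libraries. No pair of libraries was a duplicate: counts within groups differed by at least 19.8 times the sampling noise (chi-square per degree of freedom). By this measure CSD 1 and CSD 3 differed more (45.5) than control 3 did from CSD 1 (43.7) or from CSD 3 (35.1).

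No gene passed the threshold between CSD and control. Among the 13431 genes tested with edgeR's quasi-likelihood test, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.124. At an unadjusted p under 0.05 there were 1679 genes, 821 with higher and 858 with lower levels in CSD, where chance gives 672 on average. Genes vary together, so a count can lie far from that average. Other splits of the same libraries into 3 and 3 gave 157 to 1492 genes. With 1 library left out the count for CSD against control ran from 870 (without CSD 2) to 2726 (without CSD 1). Scaled to library totals alone, the split was 377 higher and 1614 lower. The 3 CSD libraries lay above all 3 controls for 1178 genes and below them for 1081. Together these were 16.8% of the tested genes, where chance gives 10%. DESeq2, fitted to all genes and not to the filtered ones alone, called 298 genes, 209 higher and 89 lower in CSD. On the filtered genes limma-voom called 0. Without control 1 edgeR called 151 genes, without CSD 1 it called 230, and without CSD 3 it called 73. With no filter it called 112, and with the replicate number as a block 104.

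The 2 genes with the smallest p among those at higher levels in CSD were ENSRNOG00000008235 and ENSRNOG00000043201. ENSRNOG00000008235 had 54.6 ± 12.5 CPM in controls and 149 ± 15.3 CPM in CSD (SD, n = 3), a log2 fold change of 1.45 (SE 0.180). ENSRNOG00000043201 had 19.1 ± 4.26 CPM in controls and 67.4 ± 19.1 CPM in CSD (SD, n = 3), a log2 fold change of 1.82 (SE 0.238). Among genes at lower levels in CSD, ENSRNOG00000008765 had 34.4 ± 4.41 CPM in controls and 15.9 ± 1.65 CPM in CSD (SD, n = 3), with a log2 fold change of -1.11 (SE 0.156). ENSRNOG00000018778 had 50.9 ± 13.4 CPM in controls and 19.8 ± 2.88 CPM in CSD (SD, n = 3), with a log2 fold change of -1.36 (SE 0.209). These values rest on 129 to 1418 reads per library. For each of these genes the CSD libraries did not overlap the controls, and none passed the threshold in the main test (edgeR, adjusted p = 0.124 for each). All 4 passed with DESeq2 (adjusted p 1.34e-09 to 4.58e-05), in edgeR with no filter (0.00810 to 0.0136) and in edgeR without control 1 (0.0371). Some but not all passed in edgeR without CSD 1 or without CSD 3. For each gene edgeR gave an adjusted p of 0.501 without control 2, 0.351 without control 3 and 0.327 without CSD 2. The adjusted p with limma-voom was 0.252 for each. The files do not pair these IDs with gene names or positions.

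Among the genes that passed the filter on low counts, most of the largest fold changes were towards higher levels in CSD. Log2 fold changes above 1 and below -1 were about as frequent, with 344 and 289 genes, but 156 genes lay above 2 against 10 below -2, and 92 lay above 3 against 3 below -3. In simulated libraries with no changed gene, in which genes varied independently, 1 gene lay above 3. The other 9 splits of the 6 libraries into 3 and 3 gave 5 to 32 genes beyond 3 in either direction, the most for controls 1 and 3 with CSD 3, against 95 for the real split. The 92 high-fold genes had a median log2 fold change of 3.89 and a highest one of 7.10. They were chosen by this fold. All 92 had an unadjusted p under 0.05, but their edgeR adjusted p ranged from 0.124 to 0.341. Each had reads in at least 1 control, and 46 averaged at least 10 CPM. Without control 1 there were 175 genes above 3 and 6 below -3, and without CSD 1 there were 61 and 26. With low-count genes included the counts were nearer to each other, at 373 and 326 with no filter and 225 and 131 with DESeq2, while on the 13431 filtered genes both gave 92 and 3.

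Together the 92 genes took 0.0570% ± 0.0527 of gene counts in controls and 1.31% ± 0.943 in CSD (SD, n = 3). A higher share in CSD follows from how the genes were chosen, so this difference was not tested. The spread within each group was wide. Controls 1, 2 and 3 had 0.113%, 0.0498% and 0.00832%, a 13.6-fold range, and CSD 1, 2 and 3 had 2.29%, 1.21% and 0.413%, a 5.55-fold range. The lowest share rested on 721 reads and the highest on 196275.

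**Figure D1:**
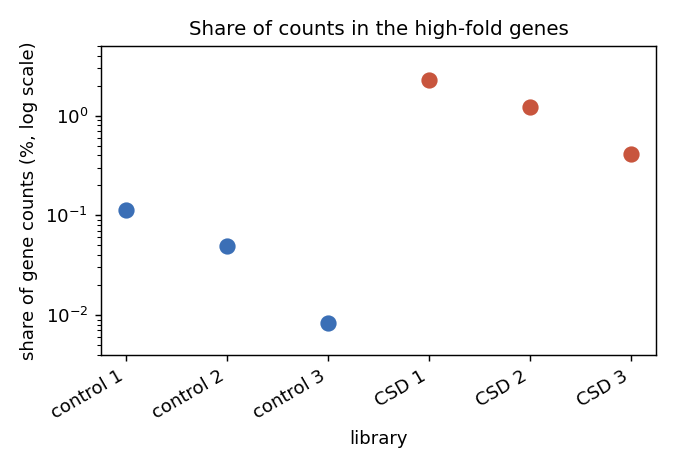
Share of gene counts (%, log scale) taken by the 92 genes with a log2 fold change above 3, with 1 point per library (blue, control; red, CSD). The CSD libraries lie at 0.413% to 2.29% and the controls at 0.00832% to 0.113%.

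The 1000 most variable genes fell into 3 modules that were formed without use of the group labels. Module 1, of 451 genes, held all 92 high-fold genes, a result that their choice by fold makes likely. Its mean log2 level was -0.89 ± 0.80 in controls and 0.89 ± 0.57 in CSD (SD, n = 3), relative to each gene's mean over the 6 libraries. All 3 CSD libraries lay above all 3 controls (exact permutation test, p = 0.1; 0.3 after Benjamini-Hochberg adjustment over 3 modules). Of its genes, 413 had a higher level in CSD, 250 of them at an unadjusted p under 0.05. Module 1 took 0.497% ± 0.212 of counts in controls and 2.27% ± 1.27 in CSD (SD, n = 3).

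Module 2, of 446 genes, ran the other way without separating the groups. Its mean log2 level was 0.46 ± 0.40 in controls and -0.46 ± 0.60 in CSD (SD, n = 3; exact permutation test, p = 0.2; adjusted 0.3). Controls 2 and 3 lay at 0.72 and 0.66 and CSD 2 and CSD 3 at -0.82 and -0.80, while control 1 lay at 0.00 and CSD 1 above it at 0.23. Of its genes, 414 had a lower level in CSD, 126 of them at an unadjusted p under 0.05. Module 2 took 1.26% ± 0.332 of counts in controls and 0.571% ± 0.325 in CSD (SD, n = 3). Module 3, of 103 genes, had a mean log2 level of -0.19 ± 0.88 in controls and 0.19 ± 0.26 in CSD (SD, n = 3; exact permutation test, p = 0.7; adjusted 0.7), and control 2 stood apart at -1.21.

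**Figure D2:**
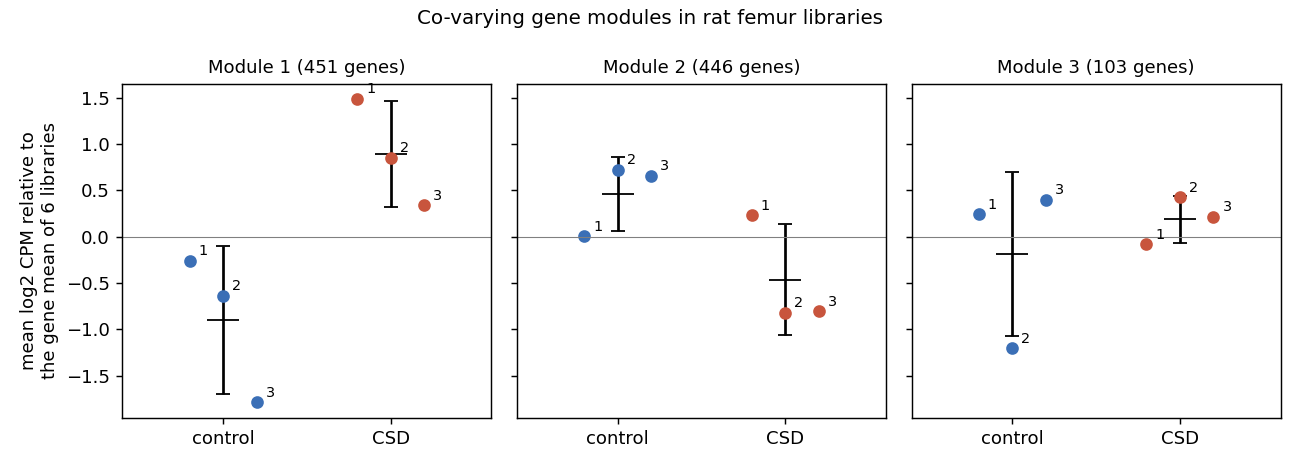
Mean log2 CPM of each module relative to the genes' means over the 6 libraries, for control (blue) and CSD (red); points are libraries with their replicate number, and bars are the group mean ± SD (n = 3). In module 1 the groups do not overlap, and in module 2 CSD 1 lies at 0.23, above control 1 at 0.00.

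Bone formation, bone resorption, PI3K/AKT and cell type genes were not compared, because the IDs could not be matched to names here. The labelled ages are 12 to 14 weeks in controls and 15 to 17 weeks in CSD. Without an assumed form of the age trend, a difference between the groups cannot be told apart from a difference in labelled age. The series description gives 12 weeks.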

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

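Leaving out the high-fold genes or the 10 most abundant genes and a prior count of 2 were chosen after the data were seen. The main count of 0 genes at an adjusted p under 0.05 stayed at 0 with DESeq2 size factors, upper-quartile factors, library totals and a CPM minimum of 1 in 3 libraries. It also stayed at 0 with limma-voom with and without quality weights and with robust edgeR. Adjusted p thresholds of 0.01 and 0.1 had to give 0, as the smallest edgeR adjusted p was 0.124. The count rose to 298 with DESeq2 fitted to all genes (209 higher, 89 lower). It rose to 112 without a filter (104 higher, 8 lower), and the cause of either rise was not tested. Of the 298 genes, 276 had an unadjusted p under 0.05 in edgeR and 71 were high-fold genes. With the replicate number as a replicate block there were 104 genes (103 higher, 1 lower). Of these, 68 were high-fold genes, which mostly ran in number order, but over all genes deviations of same-numbered libraries correlated at -0.01, -0.06 and 0.17, and control 3 and CSD 3 alone correlated best with their own number. Leaving out 1 library gave 0 to 230 genes changed, 0 to 79 higher and 0 to 194 lower; the highest values came without CSD 1 (36 higher, 194 lower) and without control 1 (79 higher, 72 lower). The 1679 genes at an unadjusted p under 0.05 became 2962 with voom quality weights and 870 (without CSD 2) to 2726 (without CSD 1) when 1 library was left out. The 92 genes with a log2 fold change above 3 and 3 below -3 became 373 and 326 without a filter, 225 and 131 with DESeq2, and 61 to 175 and 0 to 26 with 1 library left out. Counts on the 13431 filtered genes alone, added after the data were seen, were 92 and 3 in both fits and 60 and 20 without CSD 1. Mean correlation within groups exceeded that between by 0.0164; this became 0.00750 without a filter, 0.0120 to 0.0226 with 1 library left out and 0.00939 without the 92 genes. Library totals alone moved the median log2 fold change of all genes to -0.13. The 4 genes named by ID kept their direction in all 76 comparisons under alternatives and had an adjusted p under 0.05 in 20 (range 1.34e-09 to 0.501). The planned tests of gene lists, and scaling without red cell and neutrophil genes, were not run, as the IDs could not be matched to names here.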

Other observations

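The tests of the order of the high-fold genes, of library depth as their explanation, of their spread within groups, of the correlations behind a label exchange, of an exchange with CSD 2 or CSD 3 and of exchanges without the high-fold genes or without 1 library were chosen after the result was seen; the others were set before their values were known.

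The 92 high-fold genes varied together within each group. Among CSD libraries 93.5% of them ran from CSD 1 down to CSD 3, against 21.3% of the other tested genes. Among controls 64.1% ran from control 1 down to control 3, against 14.9% of the others. The others were not matched for variability. The mean of module 1, which holds all 92, ran in the same order. It was 1.49, 0.85 and 0.34 in CSD 1, CSD 2 and CSD 3. In controls 1, 2 and 3 it was -0.26, -0.64 and -1.79. The median log2 ratio of the high-fold genes was 2.14 for CSD 1 over CSD 3 (quartiles 1.64 and 2.60). For control 1 over control 3 it was 2.18 (quartiles 1.30 and 3.24). The tables argue against depth, since the highest gene total was 1.14 times the lowest. They also argue against 1 outlying library as the sole source for these genes, since the median log2 fold change was at least 3.31 without any one library. The genes were chosen with all 6 libraries, however. The excess of rises over falls shrank without CSD 1 but remained, with 60 filtered genes above 3 and 20 below -3, against 92 and 3 with all libraries. Levels fell with labelled age within both groups (2.18 and 2.14), but each labelled age is 1 library, so an effect of labelled age stays open. A candidate explanation for the spread is 1 source of RNA, such as another tissue or cell type, present in differing amounts among femurs, but the genes did not share 1 exact ratio (all tested genes had quartiles of -0.25 and 0.34 for CSD 1 over CSD 3), so this stays open, as does an effect of sleep deprivation on the difference between the groups.

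Control 1 lay between the groups. Its mean correlation with the other controls exceeded that with the CSD libraries by 0.00228, against 0.0219 and 0.0241 for controls 2 and 3, and after thinning to equal totals, which removes differences in depth, the value was 0.00232. Each exchange of labels between control 1 and a CSD library gave fewer genes at an unadjusted p under 0.05 than the 1679 of the real split. The counts were 1492 for CSD 1, 343 for CSD 2 and 691 for CSD 3. Fewer genes than the real split had been set beforehand as the limit against an exchange, but this limit allowed for no spread. With the same library left out of both splits, the exchange with CSD 1 gave fewer genes in 4 of 6 fits and more without control 1 (2613 against 2001) and without control 3 (1338 against 1168). The exchanges with CSD 2 and CSD 3 gave fewer in 5 of 6 fits each and more in the fit without that partner (1412 against 870 without CSD 2, 1607 against 1188 without CSD 3). A fit without control 1 or without the partner holds only 1 of the 2 exchanged libraries, so it cannot test their exchange. Among the fits that held both, the exchange with CSD 1 gave more only without control 3, so it stays open. The exchange with CSD 2 gave fewer in each of them (214 to 318 against 1160 to 2726), as did that with CSD 3 (336 to 510 against 870 to 2726). The rule for these exchanges, chosen after the result was seen, asked for fewer genes in all 6 fits. By that rule both stay undecided. Among only the fits that held both libraries, the counts argue against an exchange with CSD 2 or CSD 3. Without the high-fold genes the counts were 1546 for the exchange with CSD 1 and 1635 for the real split, and with them this exchange gave 8 genes beyond 3 on the log2 scale in either direction against 95. CSD 1 correlated with CSD 2 and CSD 3 at 0.965 or more and with controls 2 and 3 at 0.956 or less, as labelled, but without the high-fold genes these bounds were 0.968 and 0.967. Against controls 2 and 3, CSD 2 and CSD 3 also lay as labelled, with bounds of 0.974 and 0.947 for CSD 2 and of 0.965 and 0.955 for CSD 3. Without the high-fold genes the bounds were 0.974 and 0.960 and 0.968 and 0.962. These bounds leave out control 1, with which CSD 1 (0.969) and CSD 3 (0.971) correlated more than with each other (0.965). No biological explanation was tested for this library.

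The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For an adjusted p under 0.05, all 10 splits gave 0 genes. For an unadjusted p under 0.05, 1 of the 10 splits, the real one, gave as many as 1679 genes, and the highest other split gave 1492.

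Of the other 13339 tested genes, 69 followed the mean profile of the high-fold genes with a Pearson correlation above 0.95 across the 6 libraries. Reordering the profile over the libraries gave a median of 18 genes and, in the highest other of 720 orders, 155. Of the 720 orders, 28, the real one included, gave at least 69. This count describes the profile and is not a test of the groups. The profile came from genes chosen by their fold between the groups in these same libraries. The other genes still held those with a log2 fold change above 2 but not above 3. Genes also vary together, so the followers are not independent of each other.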
